A study of Rattus norvegicus with 8 samples.

How the data were processed

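Total RNA of the residual right kidney of 8 male rats, 4 sham-operated and 4 nephrectomized, was extracted with an RNeasy Mini Kit and labelled with Cy3 with a Low Input Quick Amp kit, per the labels' protocols. Each sample was hybridised to 1 array of a 1-colour Agilent 4x44K rat design (014879), per the file headers. The authors scanned the arrays and extracted them with Agilent Feature Extraction 10.5.1.1 under protocol GE1_105_Dec08, per the file headers, and the deposited files hold each spot's brightness as an intensity on a linear scale. The processed intensity is background-subtracted and detrended within the array by that software, per the file headers, and is not normalized between arrays. The authors also deposited a table of log2 values for 30448 probes. Set against the scanner files, it was the log2 intensity minus the array's 75th percentile, centred on each probe's median (r = 0.9999 with the same computation here, across probes), with column medians from -0.0169 to 0.0152. How its probes were chosen is not given in the sources used here, and it served only as an alternative.

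Groups were taken from the labels. The day in the source label was 1 for sham and 2 for nephrectomized samples, against 2 in the series text for both, and neither was used in a test. The slide of each array was read from the headers, and the 4 arrays of a slide shared 1 scan. No 2 files held the same values: the SD of the log2 differences between arrays was 0.243 to 0.486. The series text gives a number of 4 rats, and each label names 1 sample of 1 group.

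For the main values, log2 of the processed intensity was averaged over the spots of a probe after control spots and spots marked as outliers were removed, and each array's 75th percentile over the gene probes was subtracted. A probe with several spots counted as well above background where at least a share of 0.5 of them did. Probes well above background on all arrays of at least 1 group were kept (23982 of 41012). Probes were named by matching their RefSeq accession, without version, to a gene table of the GRCr8 assembly. This gave a symbol to 18713 probes (14400 symbols), and the other 22299 kept their accession. Because the array's annotation build (rn4, per the file headers) differs from that assembly, no coordinates are given. For each gene the brightest probe was used, which left 19865 genes, 9925 with a symbol and 9940 without, of which 70 had a missing value and were left out of the list tests. Of 110 named genes, 27 had several probes that passed the filter. The probes of 1 (Lipe) differed in sign and those of 4, among them Gsta2, Mthfd2 and Nr1d2, differed in whether they passed. Probes of near-identical family members, such as Cyp2c and metallothionein genes, can hybridise to each other's mRNA.

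Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A gene that was well above background on no array of a group, by any of its probes, has only a bound there. The bound is the other group's mean minus the dim group's mean of, per array, the higher of the probe's value and the lowest value among probes well above background. The 30 gene lists, the named genes' rule, the tests of genes and of these lists and their alternatives were set before the data were examined. Of the lists, 29 had at least 3 measured members. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and none of the 7 calls held with an estimated correlation. Members not matched to a probe by name, such as Top2a, were not analysed here. A list score is the mean over members of the log2 value minus the sham mean, and was compared by an exact permutation test.

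The named genes are the 12 largest rises and 12 largest falls among genes past the threshold, without overlap between groups, well above background on all 8 arrays and with a gene symbol, the 3 members of each list with the smallest p, and up to 3 genes per direction seen in only 1 group. In the last set 1 gene with a symbol qualified downward. Some genes that meet the rule are not reported here. Genes named outside this rule (Kif11, Mcm7, Pola1, Rfc4, Fkbp5, Tsc22d3, other clock genes and members of gene families) were chosen after their values were seen or belong to a tested set.

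The alternatives were quantile normalization, the median of probes well above background, normexp with an offset of 50 on the median spot and background intensity, the deposited table, no filter on dim probes, a filter on all 8 arrays, the mean of a gene's probes, every probe on its own, an intensity trend with robust estimation, array weights, thresholds of 0.01 and of 2-fold, the replicate number or the slide as a block, each rat left out in turn, and for lists an estimated correlation and fry. Normexp had been planned on the mean spot intensity and was run on the median one, which was the spot intensity in use here.

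The limma and camera steps were tested on simulated data: 20 sets of 8 arrays drawn from the means and moderated variances of 19795 genes, with 200 genes changed in each. Normalization, the background filter and the choice of probe were not simulated. Of genes changed by 1.25-fold, 11.7% were recovered, of those changed by 1.5-fold, 66.6%, by 2-fold, 91.2%, and by 3-fold, 97.7%, and 4.68% of the calls were false. A list of 20 genes shifted by 0.5 was called in every set, and 0 of 400 unshifted lists were. The simulated genes were independent, which real genes are not. Figures were drawn with matplotlib 3.10.9.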

Results

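Gene expression was measured in the residual right kidney of male F344/NSlc rats, an inbred strain, aged 10 weeks. There were 4 rats after a sham operation and 4 after unilateral nephrectomy, the removal of the other kidney, and the labels count them as replicates 1 to 4 of each group. The series text gives 2 days between operation and sampling, whereas the source label of the sham samples gives 1 day and that of the nephrectomized samples gives 2. The interval of the sham group is therefore unsettled, and every difference below is one between groups whose sampling may also have differed by a day. Each rat's total RNA was labelled with Cy3 and hybridised to its own array, with 4 arrays on each of 2 slides, and each slide held 2 sham and 2 nephrectomized rats. Of the 41012 gene probes, 54.8% (sham rat 1) to 65.5% (nephrectomized rat 4) were well above background, and no probe was saturated. Pairs of arrays correlated at 0.984 to 0.996 across genes, which are not independent replicates. The first principal component (32.5% of the variance) separated the groups, and the second (21.6%) set sham rat 1 apart from the other arrays. The number of arrays, 4 per group, limits the precision of every value.

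The comparison addresses how the kidney that remains compensates for the loss of its partner. Each array was scaled to its own signal, so the values are relative to the sample's other mRNA. The amount of mRNA per kidney was not measured. On this relative scale, mRNA of cell division, DNA replication and cholesterol synthesis genes was higher in the residual kidney after nephrectomy. That of glucocorticoid-responsive genes and of Cyp2c11, a cytochrome P450 typical of male rats, was lower. These list results rest on camera with a preset correlation, and none passed with an estimated correlation (adjusted p = 0.104 for each of the 4 lists). Of 19865 genes tested, 714 passed an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), 511 of them higher and 203 lower after nephrectomy. Changes upward were larger: the median called rise was 1.6-fold and the median called fall 1.41-fold, and 170 genes rose but 15 fell by at least 2-fold. The values of the 2 groups did not overlap for 2509 genes, 12.6% of those tested, against 2.86% by chance. Of the 714 genes, 420 had a symbol, and the rest were known here only by the accession of their probe. Each such accession was counted as a gene, so the counts may include a gene more than once.

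With slide as a block, limma called 802 genes, 564 higher and 238 lower, and 660 of the 714 were among them. Within slide 1 limma called 0 genes (1632 at an unadjusted p under 0.05) and within slide 2 it called 141 (2464 unadjusted). The total moved by over 1.5 times when sham rat 2, 3 or 4 was left out (397, 342 and 430 genes), or nephrectomized rat 2 or 4 (456 and 341), without the filter on dim probes (282) and with array weights (2520).

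Among genes with a symbol that were well above background on all 8 arrays, 12 are named for their rises. Ska1, a kinetochore protein, was 4.32-fold higher after nephrectomy (95% interval 3.22 to 5.78, n = 4 rats per group, adjusted p = 0.00108 by limma). Prc1, which bundles microtubules in cytokinesis, was 4.25-fold higher, and E2f1, a transcription factor of the entry into S phase, 4.03-fold. Ttk and Pbk, both mitotic kinases, were 3.98- and 3.89-fold higher, Cdca3 was 3.86-fold higher, and the cyclins Ccna2, Ccnb2 and Ccnb1 were 3.83-, 3.61- and 3.58-fold higher. Cdk1, the kinase these cyclins activate, was 3.79-fold higher, and Cenpw and Cenpt, components of the centromere, were 3.75- and 3.67-fold higher. The adjusted p of these 12 genes lay between 0.000433 and 0.00532. Every nephrectomized rat exceeded every sham rat in each, which the rule for named genes required. Background correction with normexp reduced the log2 fold change of Ska1 from 2.11 to 1.28 and that of Prc1 from 2.09 to 1.37, with both calls kept.

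**Figure D1:**
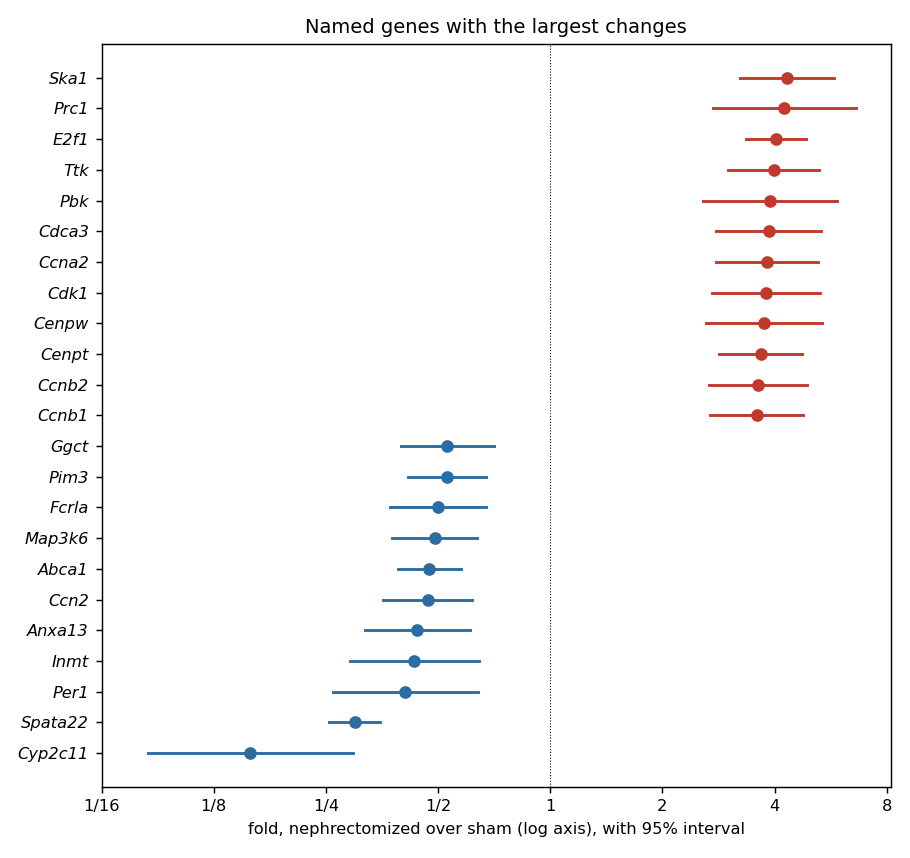
Fold change, nephrectomized over sham on a log axis, of the 12 genes with the largest rises and of 11 of the 12 with the largest falls under the rule for named genes. Points are limma estimates from 4 rats per group and lines their 95% intervals; the rises lie between 3.58- and 4.32-fold, and the largest fall is that of Cyp2c11, at 0.157 of the sham level.

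The fixed list of cell division genes rose as a group. Of its 21 measured members, 20 were higher after nephrectomy and 20 also when adjusted over the list alone. Birc5, an inhibitor of apoptosis that also acts in mitosis, was 2.83-fold higher (log2 fold change 1.5, SE 0.12, adjusted p = 0.00108) and Foxm1, a transcription factor of mitotic genes, 2.11-fold. The member that did not pass was Kif11, a spindle motor (log2 fold change 0.11, adjusted p = 0.734). The list's median log2 fold change was 1.65, with 1.24 on slide 1 and 2.17 on slide 2. camera with a preset correlation of 0.01 gave an adjusted p = 1.9e-30 (1.27e-26 with slide as a block), and adjusted p = 0.104 with an estimated correlation.

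DNA replication genes moved the same way. Of 21 measured members, 18 were higher (19 adjusted over the list alone), and the median log2 fold change was 0.84, with 0.71 on slide 1 and 0.97 on slide 2. Cdc45, part of the replicative helicase, was 2.86-fold higher (log2 fold change 1.51, SE 0.12), and Mcm3, a subunit of the same helicase, 3.17-fold (1.67, SE 0.14). A second probe of Mcm3 gave a log2 fold change of 2.65. The members that did not pass were Mcm7 (0.37), Pola1 (0.15) and Rfc4 (0.20), all positive in log2 fold change. camera gave an adjusted p = 1.62e-24 (5.22e-23 with slide as a block), and adjusted p = 0.104 with an estimated correlation.

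Some genes were well above background in one group alone, so that their change has only a lower bound. Cdt1, which loads the helicase onto replication origins, was well above background in 0 of 4 sham and 4 of 4 nephrectomized rats and was at least 3.19-fold higher (adjusted p = 0.00233). Cenpa, the histone of centromeres, was at least 2.63-fold higher (adjusted p = 0.00108) and Tonsl, a protein of replication fork repair, at least 1.93-fold (adjusted p = 0.00216). In the other direction Rhox4g, a homeobox gene, was at least 1.77-fold lower (adjusted p = 0.0118). In all, 31 called genes were seen in every nephrectomized rat and in no sham rat, and 2 the other way round. These probes lie near background, and normexp reduced their log2 fold changes from 1.76 to 0.85 for Cdt1, from 1.86 to 0.80 for Cenpa and from 1.21 to 0.40 for Tonsl. For Rhox4g it reduced the value from -1.99 to -0.37 and ended the call (adjusted p = 0.136), as did leaving out the filter on dim probes (adjusted p = 0.0506).

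Genes of cholesterol synthesis and uptake rose together. Idi1, the isopentenyl-diphosphate isomerase, was 2.25-fold higher (log2 fold change 1.17, SE 0.13, adjusted p = 0.00252) and Cyp51, the lanosterol demethylase, 2.08-fold (1.05, SE 0.16). Of 20 measured members, 10 were higher and none lower over all genes tested, and 18 were higher adjusted over the list alone. All 20 had positive log2 fold changes, with a median of 0.52 (0.44 on slide 1 and 0.63 on slide 2). camera gave an adjusted p = 1.05e-15 (1.05e-15 with slide as a block), and adjusted p = 0.104 with an estimated correlation. Abca1, which exports cholesterol from cells, fell by 1.08 on the log2 scale (SE 0.12, adjusted p = 0.00267), or by 0.61 with normexp.

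The largest fall was that of Cyp2c11, which dropped by 2.67 on the log2 scale (SE 0.40, adjusted p = 0.00942), to 0.157 of the sham level (95% interval 0.0832 to 0.296). Its nephrectomized rats spread more widely (SD 0.88, n = 4) than its sham rats (SD 0.36, n = 4). Spata22, a meiosis gene, fell by 1.74 (SE 0.10, adjusted p = 0.000433). Per1, a clock gene, fell by 1.29, Inmt, a methyltransferase of indoleamines, by 1.21 and Anxa13, an annexin, by 1.19. Ccn2, the secreted connective tissue growth factor, fell by 1.09, the kinases Map3k6 and Pim3 by 1.03 and 0.92, Fcrla, an Fc receptor-like protein, by 1.00, and Ggct, an enzyme of glutathione breakdown, by 0.92. Spata22, Cyp2c11, Abca1 and Ccn2 kept their calls without any single rat. Map3k6 lost its call without nephrectomized rat 4 (adjusted p = 0.0511), Anxa13 without sham rat 2 or 3 or nephrectomized rat 2 (0.0585 to 0.0649), Pim3 without sham rat 2 or 3 or nephrectomized rat 4 (0.0513 to 0.0568), and Fcrla without sham rat 2 or 4 or nephrectomized rat 2 or 4 (0.0545 to 0.083). Ggct (0.063 to 0.103) and Inmt (0.0725 to 0.115) each lost theirs without sham rat 2, 3 or 4 or nephrectomized rat 2, 3 or 4, and Per1 (0.0638 to 0.131) without any rat but sham rat 4. Without the filter on dim probes 9 of the 12 falls lost their calls, 5 did on the values deposited by the authors, and with slide as a block Inmt alone did (adjusted p = 0.0549). With normexp Per1 lost its call (adjusted p = 0.0612), while Anxa13 fell by 0.61 and Fcrla by 0.52.

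Genes that glucocorticoids induce were lower after nephrectomy. All 12 measured members had negative log2 fold changes, with 6 lower over all genes tested and 10 adjusted over the list alone. Klf9, a transcription factor, fell by 0.49 on the log2 scale (SE 0.06, adjusted p = 0.005), and the metallothioneins Mt2A and Mt1, which bind zinc and copper, by 0.54 (SE 0.08) and 0.50 (SE 0.08). Per1 also passed, as did Fkbp5, a co-chaperone of the glucocorticoid receptor (log2 fold change -0.73), and Tsc22d3 (-0.67), both named after their values were seen. The median log2 fold change was -0.51, with -0.48 on slide 1 and -0.51 on slide 2. camera gave an adjusted p = 9.03e-09 (1.26e-08 with slide as a block), and adjusted p = 0.104 with an estimated correlation. Mt1 lost its call without sham rat 3 (adjusted p = 0.0529), and Mt1 and Mt2A did without the filter on dim probes (0.0689 and 0.0544). Both are members of one gene family, whose probes can hybridise to each other's mRNA.

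The circadian clock list held changes in both directions. Cry1, a repressor of the clock, rose 1.49-fold (log2 fold change 0.57, SE 0.10, adjusted p = 0.0188), whereas Tef, a transcription factor of its output, fell by 0.62 (SE 0.10, adjusted p = 0.0159) and the repressor Nr1d2 by 0.37 (SE 0.07, adjusted p = 0.0275). With Per1, 3 of its 13 measured members fell and 1 rose (7 and 3 adjusted over the list alone). Its median log2 fold change was -0.20 (-0.13 on slide 1 and -0.27 on slide 2), and camera did not call it (adjusted p = 0.126, and adjusted p = 0.249 with an estimated correlation). Tef lost its call without sham rat 3 or 4 or nephrectomized rat 4 (adjusted p 0.0519 to 0.0578), Cry1 without sham rat 2, 3 or 4 or nephrectomized rat 4 (0.0508 to 0.0603), and Nr1d2 without any rat but sham rat 1 or nephrectomized rat 2 (0.0555 to 0.0978). All 3 lost their calls without the filter on dim probes (0.0726 to 0.129), Nr1d2 also on the deposited value table (0.0527), and a second probe of Nr1d2 gave -0.44 and did not pass.

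The interferon response list rose with camera (adjusted p = 9.37e-09, or 3.1e-08 with slide as a block), with adjusted p = 0.249 with an estimated correlation. All 15 measured members had positive log2 fold changes, 2 passed over all genes tested and 12 adjusted over the list alone. Ifit3, an antiviral protein, was 2.24-fold higher (log2 fold change 1.16, SE 0.19, adjusted p = 0.0126) and was well above background in 1 of 4 sham rats. Ifi44 had a log2 fold change of 0.52 and did not pass (adjusted p = 0.0718). The median was 0.59, with 0.89 on slide 1 and 0.35 on slide 2. The call of Ifit3 was lost without the filter on dim probes (adjusted p = 0.0549), and normexp reduced its log2 fold change to 0.53.

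The tubular injury and repair list shifted upward by less. Its median log2 fold change was 0.15 (0.20 on slide 1 and 0.21 on slide 2), and 2 of its 13 measured members rose (3 adjusted over the list alone). These were Fgb, the fibrinogen beta chain, 1.77-fold (log2 fold change 0.82, SE 0.14, adjusted p = 0.0181), and Spp1, which encodes osteopontin, 1.43-fold (0.52, SE 0.10, adjusted p = 0.0293), whereas Krt18, a keratin, did not pass (0.36, adjusted p = 0.127). camera gave an adjusted p = 0.00693 (0.00474 with slide as a block), and adjusted p = 0.104 with an estimated correlation. Fgb lost its call without sham rat 2 or 3 or nephrectomized rat 4 (adjusted p 0.0501 to 0.0594), and Spp1 without any rat but sham rat 2 or nephrectomized rat 2 (0.0562 to 0.0978). Both lost it without the filter on dim probes (0.0757 and 0.122), and Spp1 on the deposited value table (0.0568).

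The glycolysis and hypoxia response list lay at the threshold (camera adjusted p = 0.0499, or 0.0455 with slide as a block), with adjusted p = 0.176 with an estimated correlation. Its median log2 fold change was 0.15, with 0.12 on slide 1 and 0.19 on slide 2. Of 15 measured members, Ldha, the lactate dehydrogenase A chain, rose 1.22-fold (log2 fold change 0.28, SE 0.05, adjusted p = 0.0275), and Ankrd37, an ankyrin repeat protein, fell by 0.37 (SE 0.07, adjusted p = 0.0275). Hk1, a hexokinase, had a log2 fold change of 0.27 and did not pass (adjusted p = 0.0597). Adjusted over the list alone, 5 rose and 1 fell. The list's call was lost without any rat but sham rat 1 or nephrectomized rat 2 (adjusted p 0.0563 to 0.106) and under most other settings (0.0519 to 0.0883). Ldha lost its call without any rat but sham rat 1 or nephrectomized rat 3 (0.0593 to 0.103), and Ankrd37 without any but nephrectomized rat 1 or 3 (0.0529 to 0.0883), and both did without the filter on dim probes (0.147 and 0.129).

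**Figure D2:**
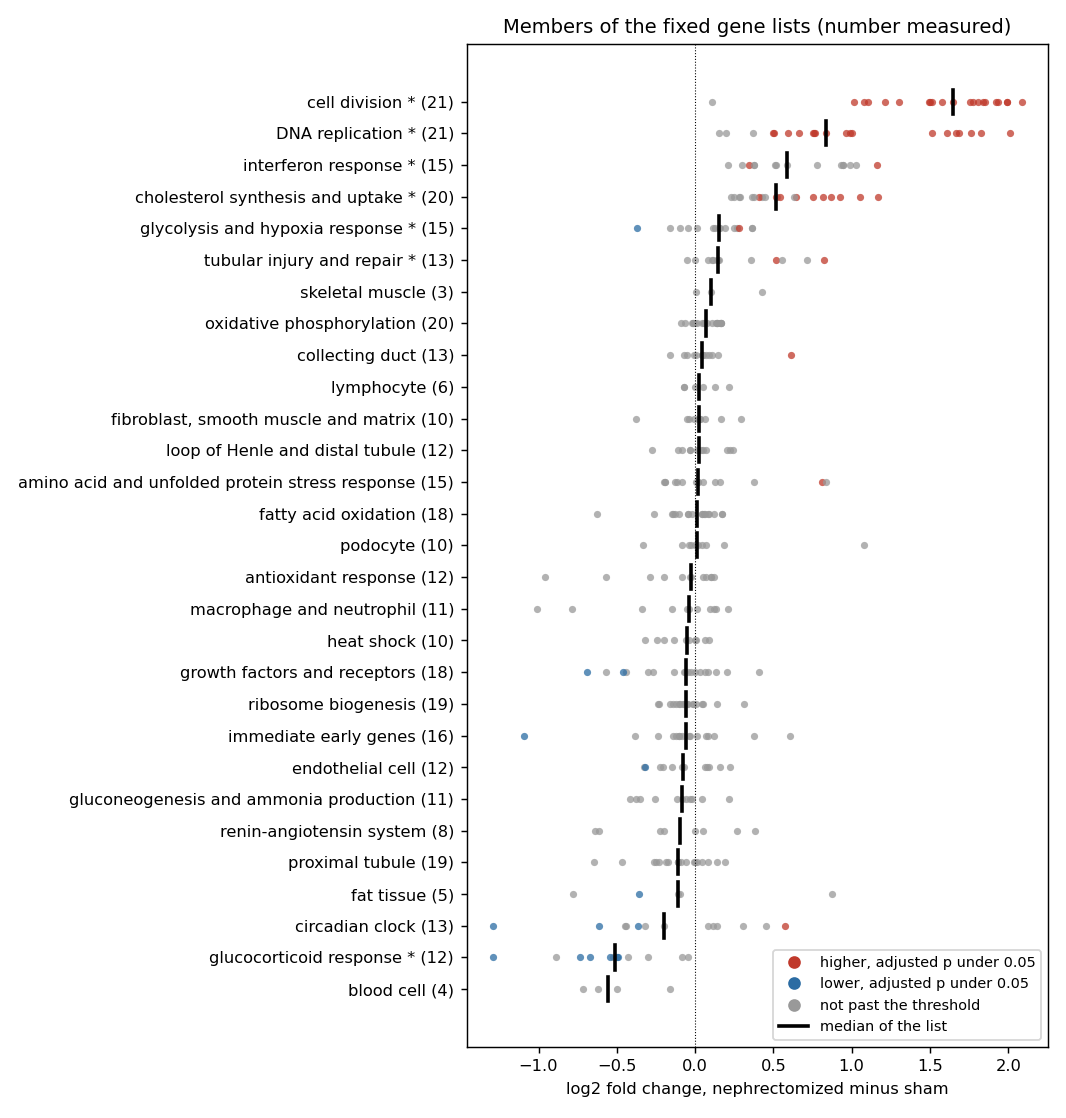
Log2 fold change, nephrectomized minus sham, of each measured member of 29 fixed gene lists, with the number measured in brackets and the lists in order of their median (black bar). Red and blue points passed an adjusted p of 0.05, grey points did not, and an asterisk marks the 7 lists that camera called with a preset correlation; the medians run from 1.65 for cell division to -0.56 for blood cell genes, a list of 4 that was not called. Cdt1 and Mthfd2 are drawn at their fitted values, although neither probe was well above background in any sham rat.

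The other 22 lists measured did not pass, and with slide as a block the same 7 lists and no other were called. Among metabolic and stress lists, the median log2 fold changes were -0.06 for ribosome biogenesis (19 measured), 0.01 for fatty acid oxidation (18), 0.07 for oxidative phosphorylation (20), -0.08 for gluconeogenesis and ammonia production (11), 0.02 for the amino acid and unfolded protein stress response (15), -0.05 for heat shock (10) and -0.03 for the antioxidant response (12). Their camera adjusted p lay between 0.104 and 0.947. Gluconeogenesis and ammonia production passed with normexp (adjusted p = 0.0215), and oxidative phosphorylation without the filter on dim probes (0.0478) and without nephrectomized rat 1 (0.0408). The median for fatty acid oxidation was positive, and its mean, -0.04, and its camera direction were negative. In these lists 1 gene passed on its brightest probe, Mthfd2, a mitochondrial folate enzyme. It was higher after nephrectomy (adjusted p = 0.044 by limma), but its probe was well above background in 0 of 4 sham rats, so that no size is given. It lost its call with slide as a block (adjusted p = 0.0596), with normexp (0.06) and without any rat but sham rat 1 (0.0795 to 0.128). Its other 2 probes did not pass, and without the filter on dim probes the adjusted p was 0.151. Nop56, a nucleolar protein, had a log2 fold change of 0.32 (adjusted p = 0.0535), and Gclc, which makes glutathione, -0.96 (adjusted p = 0.208). Gsta2, of the antioxidant response list, did not pass on its brightest probe (log2 fold change -0.20, adjusted p = 0.218 by limma). A second probe of Gsta2 fell by 0.48 (adjusted p = 0.00576 by limma), and the mean of its probes by 0.34 (0.00796).

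Signalling lists were not called either. The median log2 fold change was -0.06 for immediate early genes (16 measured), where Ccn2 fell and Atf3, a stress-induced transcription factor, had a log2 fold change of 0.37 (adjusted p = 0.12). It was -0.06 for growth factors and receptors (18), where Errfi1, an inhibitor of the EGF receptor, fell by 0.69 (SE 0.12, adjusted p = 0.0157) and Hgf, the hepatocyte growth factor, by 0.46 (SE 0.09, adjusted p = 0.0271). It was -0.10 for the renin-angiotensin system (8), where Ace, the angiotensin-converting enzyme, had a log2 fold change of -0.62 (adjusted p = 0.193). Errfi1 lost its call without sham rat 3 (adjusted p = 0.0523), and Hgf without any rat but nephrectomized rat 2 (0.0563 to 0.0921), with normexp (0.456, log2 fold change -0.14) and with an intensity trend and robust estimation (0.062), and both lost it without the filter on dim probes (0.0698 and 0.119). The camera adjusted p of these lists were 0.369, 0.104 and 0.513.

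Markers of kidney segments gave medians of -0.11 for the proximal tubule (19 measured, camera adjusted p = 0.104), 0.02 for the loop of Henle and distal tubule (12, 0.947), 0.05 for the collecting duct (13, 0.423) and 0.01 for podocytes (10, 0.947). The proximal tubule list passed downward with normexp (adjusted p = 0.0276), with array weights (0.0287) and without nephrectomized rat 3 (0.00811). Aqp4, a water channel of the collecting duct, rose 1.53-fold (log2 fold change 0.61, SE 0.11, adjusted p = 0.0253). It lost its call without sham rat 2, 3 or 4 or nephrectomized rat 3 or 4 (adjusted p 0.0594 to 0.0835). Slc22a2, a cation transporter of the proximal tubule, had a log2 fold change of -0.65 (adjusted p = 0.254). Markers of other cells gave medians of -0.08 for endothelial cells (12, 0.305), 0.03 for fibroblasts, smooth muscle and matrix (10, 0.947), -0.04 for macrophages and neutrophils (11, 0.484), 0.03 for lymphocytes (6, 0.947), -0.56 for blood cells (4, 0.257), -0.11 for fat (5, 0.171) and 0.10 for skeletal muscle (3, 0.484). The blood cell list passed without sham rat 3 (median -1.01, adjusted p = 0.0427), and without sham rat 4 its median was -0.02 (adjusted p = 0.688). No adrenal gland marker passed the filter, with 8 of 10 on the array. Vwf, the von Willebrand factor, fell by 0.32 (adjusted p = 0.0467), and lost its call with slide as a block (adjusted p = 0.06) and without any single rat (0.0593 to 0.144). Pnpla2, a triglyceride lipase, fell by 0.36 (adjusted p = 0.023) and lost its call without sham rat 3 or 4 or nephrectomized rat 1, 2 or 4 (0.0519 to 0.0819). Without the filter on dim probes Aqp4, Vwf and Pnpla2 did not pass (0.104, 0.191 and 0.118). The neutrophil genes S100a8 and S100a9 had log2 fold changes of -1.01 and -0.78 that did not pass (adjusted p = 0.121 and 0.128) but did with slide as a block (0.0172 and 0.0106).

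**Figure D3:**
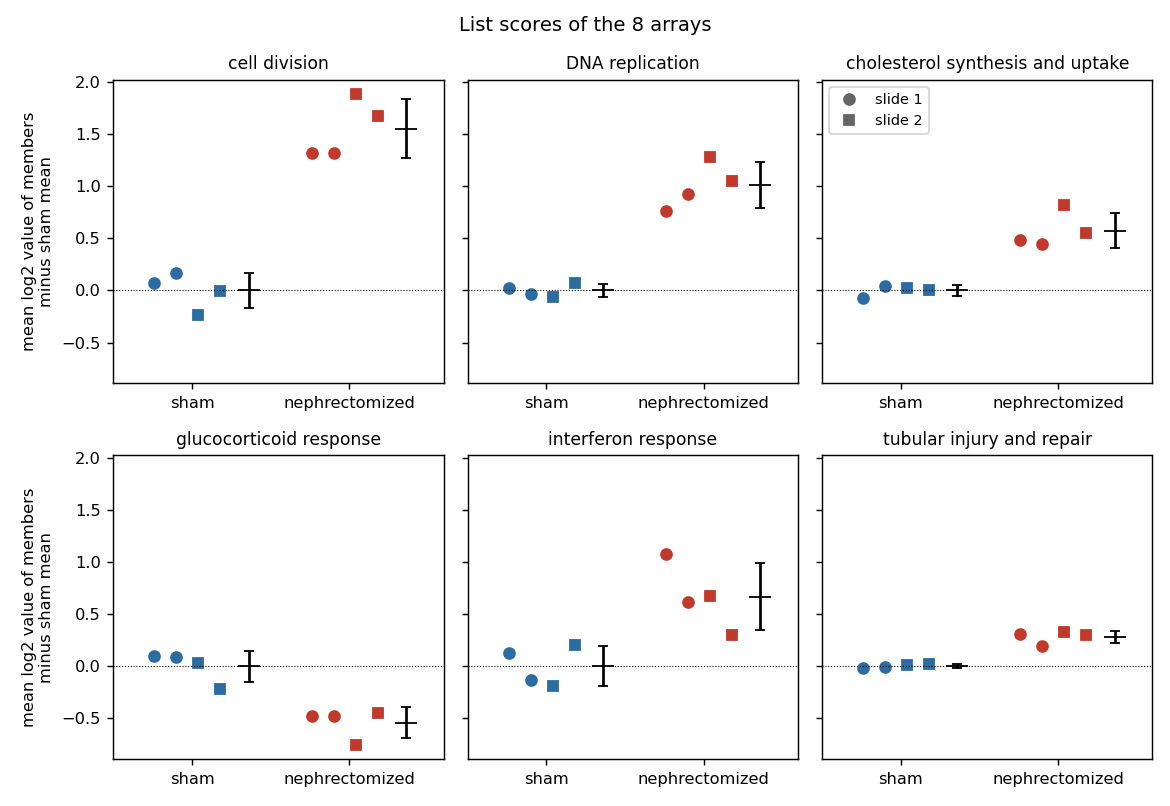
Mean log2 value of a list's members minus the sham mean, for each of the 8 arrays and 6 of the called lists, with circles for slide 1 and squares for slide 2, and bars for the group mean and SD (n = 4). The nephrectomized arrays lie above all sham arrays for cell division (mean 1.55, SD 0.28) and below them for the glucocorticoid response (mean -0.54, SD 0.15).

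An exact two-sided permutation test of the list scores of the 8 arrays gave p = 0.0286 for each of the 7 called lists, the smallest value that 4 against 4 allows. The same p was reached by 5 lists that camera did not call, and adjusted over the 29 lists it was 0.0691, so that no list passed by this test. Because the called lists were already at the smallest value, a larger shift could not have made them pass. The adjusted result therefore does not bear on the size of their shifts.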

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

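The single-sample values below were found by comparing the gap of the lowest or highest of 4 rats to its nearest neighbour with the range of the group, where a ratio above Dixon's 95% critical value stands out. Chance gives about 1 in 20 such groups, or 5%. Among 220 groups of named genes 9 stood out, among 58 groups of list scores 8, and among 6 groups of array measures 2. The tests of dividing leukocytes, of the slide for the cholesterol list and of the LXR targets with Abca1 were chosen after the results were seen. The test of the LXR targets without Abca1 was set after the fall of Abca1 had been seen.

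Ccna2 was 0.31 below the median of the other sham rats in sham rat 3 on the log2 scale (ratio 0.875), and Ccn2 was 0.72 below in sham rat 4 (0.838). Fbl, a nucleolar protein, was 0.14 above in sham rat 3 (0.848), Nr1d2 0.14 below in sham rat 1 (0.842) and Mb, myoglobin, 0.13 below in sham rat 4 (0.839). Lipe, a lipase, was 4.02 below in sham rat 3 (0.901), which turned the sign of its uncalled log2 fold change. Among nephrectomized rats, Ephx1, an epoxide hydrolase, was 0.53 above the others in rat 3 (0.946), Mt2A 0.26 below in rat 3 (0.913) and Clic5, a podocyte gene, 1.1 below in rat 1 (0.973).

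Among list scores, the amino acid and unfolded protein stress response stood 0.39 below the others in sham rat 2 (ratio 0.955), the renin-angiotensin system 0.41 below in sham rat 1 (0.925), endothelial genes 0.05 below in sham rat 3 (0.833) and fat genes 0.50 below in sham rat 3 (0.843). In nephrectomized rat 3 the glucocorticoid response stood 0.28 below (0.879), proximal tubule genes 0.26 above (0.852) and loop of Henle and distal tubule genes 0.16 below (0.959). Tubular injury and repair genes stood 0.11 below in nephrectomized rat 2 (0.83). The spike-in controls were 1.14 brighter on the log2 scale than on the median array for sham rat 1 (ratio 0.937) and 0.985 brighter for nephrectomized rat 1 (0.899), so that both groups held 1 such array.

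The first pattern weighed is the count of 714 changed genes with the rise of cell division and DNA replication genes. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many genes, the real one, and the highest of the others gave 192. Chance is thus unlikely but not excluded, because 1 in 35 is the smallest share that these splits allow. A shift common to a slide cancels, because each slide held equal numbers of rats of both groups. Both lists had medians of at least 0.71 on each slide, which argues against the slide as the cause. Without sham rat 1 both passed with at least 0.956 of their median shift, which argues against its array. Dividing leukocytes moving into the kidney may contribute: the 17 leukocyte markers measured had a median log2 fold change of 0.00108, but they went both ways (9 positive, 8 negative), and resident leukocytes would hide a small share of dividing ones. Division of kidney cells after loss of the other kidney remains an untested hypothesis, and the possible difference of a day in sampling is open too.

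The second is the fall of glucocorticoid-responsive genes. A shift common to a slide cancels here too, and the medians were -0.48 or lower on both slides. The array of sham rat 1 is argued against by a median of -0.51 and a camera adjusted p = 6.72e-07 without it. Sampling at another phase of the day may account for it: Dbp, Tef, Nr1d1, Nr1d2, Per2 and Per3, the output limb of the clock, minus Bmal1, Clock, Npas2, Nfil3 and Cry1, its positive limb and genes in phase with it, shifted by -0.756 after nephrectomy (exact interval -1.1 to -0.323 at 97.1% confidence, exact rank test p = 0.0286, the smallest possible). All 6 output genes were lower and all 5 others higher in log2 fold change (means -0.40 and 0.32), though 3 of the 11 passed singly, and the shift was -0.58 on slide 1 and -0.85 on slide 2. The counts and median of the clock list as a whole had been seen when this test was set. A change of the kidney's clock or of circulating glucocorticoids after nephrectomy would look the same. The time of day at sampling, the possible difference of a day between operation and sampling, and an effect of the operation therefore all stay open.

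The third is the rise of cholesterol synthesis genes. The median was at least 0.435 on each slide, so the rise did not come from 1 slide alone. Lower sterol in the cells would lower the targets of the LXR receptors, which sense sterols: the 8 measured of 12 targets listed for this test shifted by -0.0292 as a mean (exact interval -0.108 to 0.061 by the same method, exact p = 0.686), above the bound of -0.2 set beforehand for excluding it. The bound was set before these targets were tested, but after the fall of Abca1, itself a target, had been seen and had passed over all genes. The fault lay in the list, which left out Abca1, so that the bound could exclude nothing. With Abca1 the interval of the 9 targets crossed the same bound (shift -0.151, -0.241 to -0.0574, exact p = 0.0286). The shift of the set therefore rests on 1 gene known beforehand. Without it 5 targets were negative and 3 positive in log2 fold change. Apoe fell by 0.34 (adjusted p = 0.0296 by limma) and Srebf1 rose by 0.29 (adjusted p = 0.0334 by limma). These targets went both ways, so that their mean near 0 cannot decide the question. The explanation stays open, as does a demand of dividing cells, which was not tested, and the possible difference of a day in sampling.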

How the results depend on the processing

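All alternatives below were planned, except that normexp was run on the median spot intensity instead of the mean one. The count of changed genes moved by over 1.5 times from 714 (511 higher, 203 lower) to 282 (244 and 38) without the filter on dim probes, 2520 (1391 and 1129) with array weights, 296 (243 and 53) with the replicate block, 185 (170 and 15) at 2-fold or more and 260 (227 and 33) at an adjusted p of 0.01. On the deposited value table the genes lower were 103. For the filter, array weights, the deposited table and the replicate block the cause was not tested. Without the filter 86.5% of calls were higher, with array weights 55.2%, against 71.6%. Leaving out each rat in turn gave 341 to 666 genes, 279 to 462 higher and 57 to 214 lower, with fewer samples. Under the other normalizations the median log2 fold change of all genes was at most 0.0156. The replicate numbers did not pair the rats: deviations of same-numbered rats correlated at 0.103, 0.0112, 0.101 and -0.0176, and 1 of 4 sham rats correlated best with the nephrectomized rat of its own number. With the replicate block 6 lists were called and 22 of the named genes lost their calls, among them 1 of the 12 rises (Pbk, adjusted p = 0.0512), Mt1 (0.0843), Mt2A (0.0741) and 7 of the 12 falls under the rule for named genes, such as Cyp2c11 (0.0535) and Ccn2 (0.0692).

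Of 7 lists called, 6 to 8 were called under the other settings, except 0 with an estimated correlation, which was -0.019 to 0.639 over the 7 lists, and 13 with fry, which does not compare a list with other genes. For tubular injury and repair (-0.019) and glycolysis and hypoxia (-0.00594) the estimate lay below the preset 0.01. Their unadjusted camera p still rose, from 0.00143 to 0.015 and from 0.012 to 0.0365, so a higher correlation was not what raised it. Glycolysis and hypoxia lost its call most often. The other 6 kept theirs in all settings but the estimated correlation.

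Of 53 called named genes, 24 kept their call in every setting run on them, and none changed sign. Over the 1001 alternative values 186 lost the call. Normexp, whose offset pulls dim probes together, weakened dim genes, and signal over background limits these. On the deposited table, calls ended for Hgf, Ldha, Ankrd37, Mthfd2 and Vwf among others. Among 57 genes not called, 36 of 1080 values passed, 21 of them with array weights.

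Uncalled medians near 0 changed sign, with the cause not tested. With array weights, fatty acid oxidation was -0.024, the amino acid and unfolded protein stress response -0.0259, fibroblast genes -0.0432, lymphocyte genes -0.0153 and Mb -0.00759. With normexp, loop of Henle genes were -0.031, fibroblast genes -0.000351 and Mb -0.00255. With quantile normalization, loop of Henle genes were -0.0115 and Mb -0.0022. The antioxidant response was 0.016 on the deposited table and 0.0143 without the filter, where macrophage and neutrophil genes were 0.0103. Without each rat in turn the ranges were -0.0476 to 0.0498 for fatty acid oxidation, -0.0555 to 0.0466 for the amino acid and unfolded protein stress response, -0.0919 to 0.0344 for the antioxidant response, -0.194 to 0.037 for the renin-angiotensin system, -0.0206 to 0.0647 for loop of Henle genes, -0.0509 to 0.0739 for podocyte genes, -0.0551 to 0.0792 for fibroblast genes, -0.111 to 0.0723 for macrophage and neutrophil genes, -0.0676 to 0.0885 for lymphocyte genes, -0.00233 to 0.387 for Cd3g, -0.152 to 1.3 for Lipe and -0.0294 to 0.0202 for Mb.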

Other observations

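Gene families grouped by the start of their symbol were tested after the data were examined, with camera at the preset correlation over 101 families of at least 10 genes. There were 7 families past an adjusted p of 0.05, 5 upward and 2 downward, and none with an estimated correlation (adjusted p = 0.397 or higher). Centromere protein genes (Cenp) had a median log2 fold change of 1.56 (0.77 with normexp), with 9 of 12 higher, among them Cenpm, 3.51-fold. Of 12 tubulin genes 8 were higher, such as Tubb6 (1.53-fold, adjusted p = 0.00233 by limma) and Tubb2b (1.5-fold), with a median of 0.44. Of 23 kinesin genes 7 were higher, among them Kif23 (2.26-fold), with a median of 0.18, and Kif23 did not pass with slide as a block (adjusted p = 0.0601 by limma). Of 13 genes named Rad, several of which act in DNA repair, 4 were higher, such as Rad54l (2.07-fold). The 38 genes of the Ndu group, mostly subunits of respiratory complex I, had a median of 0.08 and 1 called member, and their shift did not pass with normexp (adjusted p = 0.129).

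Cytochrome P450 genes shifted downward (28 genes, median -0.13, adjusted p = 0.032), with 5 lower and 3 higher. Besides Cyp2c11, Cyp2e1 fell by 0.68 on the log2 scale (SE 0.07, adjusted p = 0.0016 by limma), Cyp2d2 by 0.68 and Cyp2d4 by 0.55, and Cyp4f1 by 0.36. Cyp26b1, which degrades retinoic acid, was 2.01-fold higher (adjusted p = 0.00268), and Cyp17a1 and Cyp51 also rose. Aldehyde dehydrogenase genes (17, median -0.15, adjusted p = 0.032) held 1 called gene, Aldh1a1, which makes retinoic acid and fell by 0.30 (SE 0.05, adjusted p = 0.0198). Klf15, a transcription factor that glucocorticoids induce and that was not in the fixed list, fell by 0.87 (SE 0.07, adjusted p = 0.00108). These directions were the same with quantile normalization, the median of detected probes and normexp for the families as sets.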
